A study of Mus musculus and Homo sapiens with 32 samples.

How the data were processed

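Bulk mRNA sequencing was carried out on HK-2 cells and on whole kidneys of Pcmt1 wild-type and knockout mice. It also covered kidneys of Pcmt1 fl/fl and tKO mice after sham surgery or unilateral ureteral obstruction (UUO). Per the labels' protocols, total RNA was extracted with TRNzol Universal Reagent and libraries were made with an ABclonal mRNA kit for Illumina sequencing. The labels do not spell out tKO. The submitters' processing notes name fastp, HISAT2 and StringTie, with no versions, and the builds GRCm38/mm10 and hg38/GRCh38. The counting step, the gene annotation, the strand setting and any filter on genes were not given in the sources used here.

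The deposited tables give, for each gene and library, a read count and an FPKM (fragments per kilobase of gene, scaled by library depth), both computed by the authors. The deposited counts are whole numbers that were not normalized. The HK-2 table lists 379 genes and the table of knockout and wild-type kidneys 410 genes. Each listed gene differs between the group means of FPKM by at least 2.0-fold in HK-2 and 1.501-fold in kidney, and the higher group mean is at least 1.005 and 1.002. These tables were therefore treated as the authors' lists of changed genes, chosen on the same libraries. The table of the obstruction experiment lists 57180 genes, of which 525 have no symbol and 233 symbols occur more than once. No column of values was left without a sample.

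Column totals of a partial table are not its depth. For HK-2 and kidney, the library depth behind the FPKM was recovered from the ratio of count to FPKM in genes with at least 20 counts and from gene lengths, with a relative tolerance of 0.001 for a shared depth. Applied to the full table of the obstruction experiment, the same procedure returned the column totals with a largest relative error of 1.4e-07. The recovered depth was used without a further scaling factor in these 2 tables, a departure from the planned TMM normalization that was made after the tables had been seen. TMM, RLE and column totals on the listed genes were run as alternatives.

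Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Genes were kept by filterByExpr with the groups given, dispersion was estimated from all libraries of a table, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. HK-2 cells (3 against 3 libraries) and kidneys (4 against 4) were fitted separately. The 18 libraries of the obstruction experiment (6 groups of 3) were fitted together with TMM normalization, which left 19256 genes and 12 residual degrees of freedom. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The biological coefficient of variation was 0.217 in HK-2, 0.357 in kidney and 0.283 in the obstruction experiment. CPM in the text are counts scaled to the recovered depth (HK-2, kidney) or of the TMM-scaled library size (obstruction experiment), given as mean ± SD. Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group, which covers counting error only.

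The 37 gene lists were written before the data were examined, as were the groups, the designs, the rule for named genes and most of the other settings tried. They cover fibrillar collagen and matrix, basement membrane, TGF-beta ligands, receptors and Smads, TGF-beta responsive genes, myofibroblast and stromal genes, epithelial-mesenchymal transition transcription factors, tubular injury, nephron segments (proximal tubule, loop of Henle and distal convoluted tubule, collecting duct, podocyte), endothelium, leukocytes (macrophage and monocyte, MHC class II, T, NK and B cell, neutrophil), inflammatory cytokines, interferon response, fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrially encoded genes, cell cycle, unfolded protein response, heat shock, NRF2, p53, cholesterol biosynthesis, glycolysis and hypoxia, protein repair and methyl cycle, circadian clock, immediate early genes, other tissues (adipose, adrenal, urothelium, erythroid) and genes that differ between the sexes in kidney. In the obstruction experiment, lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, then with camera at a correlation estimated from the data, and with fry, which asks whether a list moves one way and does not compare it with other genes. Lists were not set-tested in the partial tables.

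The genes named in each comparison were Pcmt1, Tgfb1, Tgfbr1, Tgfbr2, Smad2, Smad3, Smad4 and Smad7, the 12 largest increases and 12 largest decreases among genes past the threshold with a mean CPM of at least 5 and no overlap between the libraries of the groups, and up to 4 members of each list with the smallest p. For UUO against sham in tKO and for the interactions the numbers were 8 and 8, and the interactions had no overlap condition. Gene models without a name were left out.

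Other settings chosen at that point were RLE size factors, column totals, no low-count filter, DESeq2 1.42.0, the replicate number as a block, fits on only the 2 groups compared, and leaving out each library in turn. Fits without the mitochondrially encoded genes and TMM on the listed genes were added after the data had been seen. Libraries of the same replicate number in different groups did not deviate together, so the numbers were not used as pairs. No pair of libraries in a group differed by as little as sampling noise: the smallest chi-square per degree of freedom was 18.3.

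The test was checked on simulated counts with 200 changed genes per comparison. In HK-2 86% of 2-fold and 99% of 4-fold changes were recovered, in kidney 57% and 98%, for UUO against sham in fl/fl 41% and 92%, and for the interaction of genotype and UUO 12% and 77%. False calls made up 1.6%, 0.6%, 3.6% and 8.2% of the calls. Coordinates are from the annotation of GRCm38 (mouse) by gene identifier, or from the HK-2 table (hg38). The loci printed in the table of the obstruction experiment shared a start or end with that annotation for only 2.83% of the 51933 identifiers found in both. No coordinates in the text were therefore taken from them. They served to find overlapping genes within that table and to check the procedure for the recovered depth. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.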

Results

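Gene expression was measured by mRNA sequencing in 3 settings of deficiency of PCMT1, the enzyme that methylates isoaspartyl residues and so starts their repair in aged proteins. The settings were HK-2 human proximal tubule cells with and without PCMT1 knockout (3 libraries each), whole kidneys of Pcmt1 knockout and wild-type mice (4 libraries each), and kidneys of Pcmt1 fl/fl and tKO mice. The fl/fl and tKO kidneys were studied after sham surgery, after unilateral ureteral obstruction (UUO), a model of renal fibrosis, and after UUO with LY2109761, an inhibitor of the TGF-β receptor kinases. Sham and UUO mice without LY2109761 received DMSO, and each of these 6 groups held 3 libraries. Library depth was 13785470 to 16343512 reads in HK-2, 15988073 to 20004978 in kidney and 13015669 to 19565376 in the obstruction experiment. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

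The targeted gene was examined first. In the obstruction experiment Pcmt1 (ENSMUSG00000019795, GRCm38 chromosome 10, 7629373 to 7681136) stood at 45.1 ± 3.38 CPM in fl/fl sham kidneys and 39.1 ± 3.31 CPM in fl/fl UUO kidneys (SD, n = 3). It stood at 25.6 ± 0.77 CPM in tKO UUO kidneys and 26.2 ± 2.73 CPM in tKO UUO kidneys with LY2109761, against 32.0 ± 6.67 CPM in fl/fl UUO kidneys with LY2109761. In the tKO sham group 2 libraries had at most 24.3 CPM, while the library labelled tKO sham replicate 1 had 49.3 CPM, above all 3 fl/fl sham libraries (42.8 to 49.0 CPM). The genotype difference was −0.48 on the log2 scale in sham (SE 0.23, edgeR adjusted p = 0.1822), −0.61 in UUO (SE 0.23, edgeR adjusted p = 0.0818) and −0.29 with LY2109761 (SE 0.23, edgeR adjusted p = 0.5354), none past the threshold with all libraries. In sham it was −0.94 without the library labelled tKO sham replicate 1 and passed (edgeR adjusted p = 0.002), and in UUO a fit on only the 2 groups gave −0.63 (edgeR adjusted p = 0.0194). Every direction drawn from the tKO sham group below includes that library. PCMT1 was not among the genes listed for HK-2 cells or whole kidney.

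The share of counts on mitochondrially encoded genes differed widely between the groups. It was 30.8% to 35.5% in fl/fl sham libraries, 33.7% in the library labelled tKO sham replicate 1, and 49.7% and 69.5% in tKO sham replicates 2 and 3. After UUO it was 7.43% to 7.67% in fl/fl and 9.88% to 16.2% in tKO, and with LY2109761 12.2% to 16.4% in fl/fl and 12.4% to 18.8% in tKO. The TMM factors moved with it, from 0.352 in tKO sham replicate 3 to 1.329 in tKO UUO replicate 1. The first principal component held 58.6% of the variance and parted sham from UUO libraries.

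**Figure D1:**
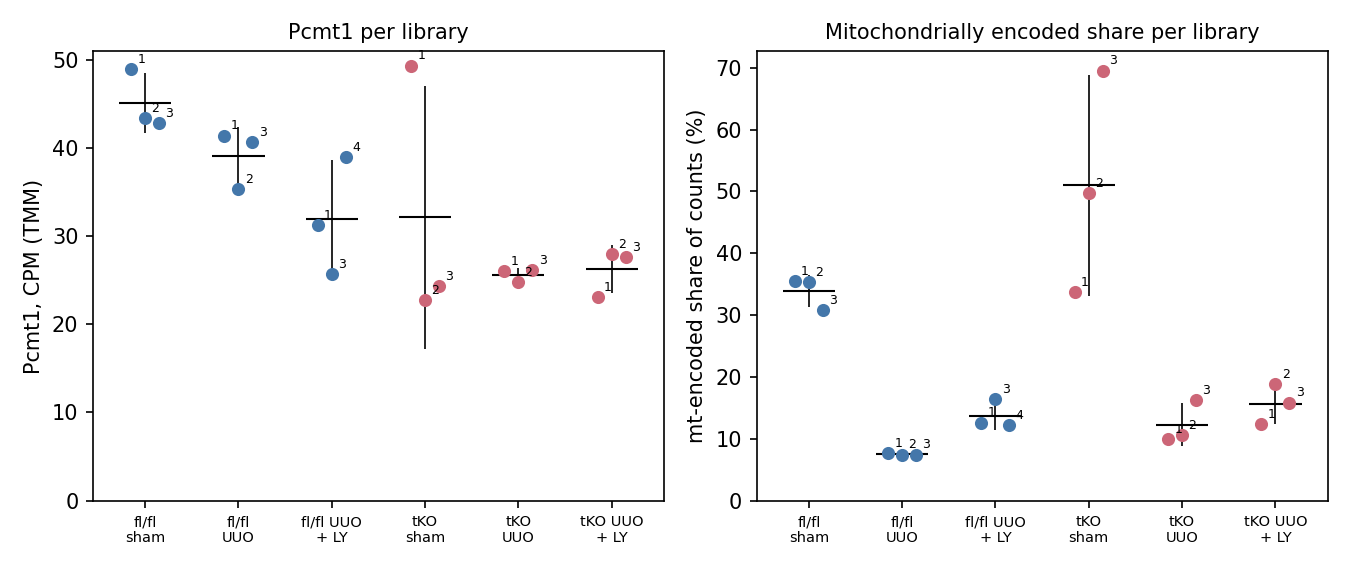
Pcmt1 in CPM (counts scaled to library depth) and the share of counts on mitochondrially encoded genes (%) in each library of the obstruction experiment, by group, with replicate numbers beside the points, horizontal lines for the group means and vertical bars for 1 SD. The library labelled tKO sham replicate 1 sits at 49.3 CPM, while the other tKO sham libraries have at most 24.3 CPM and mitochondrial shares of 49.7% and 69.5%.

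Obstructed and sham kidneys were first compared in fl/fl mice. Tubular injury genes rose in most cases. Havcr1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578), which encodes the injury marker KIM-1, rose by 9.28 on the log2 scale (SE 0.34, edgeR adjusted p = 4.2e-10), from 2.32 ± 0.781 to 1444 ± 234 CPM. The matrix metalloproteinase gene Mmp7 rose by 8.98 (SE 0.80, edgeR adjusted p = 7.8e-07) and the adhesion molecule gene Vcam1 by 5.87 (SE 0.32, edgeR adjusted p = 1.7e-08). Of 26 tubular injury genes tested 24 rose (24 adjusted over the list alone, camera adjusted p = 1.2e-30), and their median change was 3.27. Kcnt1 (ENSMUSG00000058740, chromosome 2, 25863734 to 25918273), a sodium-activated potassium channel gene, fell from 46.0 ± 14.6 to 0.812 ± 0.499 CPM (log2 −5.78, SE 0.66, edgeR adjusted p = 6.8e-06). S100g, which encodes a calcium-binding protein of the distal nephron, dropped by 4.61 (SE 0.28), and Egf, the distal tubule growth factor gene, dropped by 4.29 (SE 0.42).

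Losses reached the proximal tubule, the loop and distal tubule, and the collecting duct. Of 34 proximal tubule genes 28 fell and 1 rose (32 and 1 adjusted over the list alone, camera adjusted p = 4.6e-14), among them Ggt1 (γ-glutamyltransferase, −2.29) and Slc22a7 (an organic anion transporter, −5.26). Of 16 genes of the loop of Henle and distal convoluted tubule 12 fell and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 1.2e-09). All 16 collecting duct genes fell (16 adjusted over the list alone, camera adjusted p = 8.6e-16), among them Aqp4 (a basolateral water channel, −4.48) and Hsd11b2 (the cortisol-inactivating enzyme, −2.33). Pvalb was at 0 in all UUO libraries and at least 184-fold lower than in sham. Of 12 podocyte genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), and of 15 endothelial genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), lists that camera did not call (adjusted p = 0.1133 and 0.4864).

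Most matrix genes and part of the TGF-β pathway rose with obstruction. Of 28 genes of fibrillar collagen and matrix 25 rose and 1 fell (25 and 1 adjusted over the list alone, camera adjusted p = 1.7e-19), with a median change of 2.02. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), a chain of type I collagen, rose from 21.4 ± 6.07 to 273 ± 39.7 CPM (log2 3.68, SE 0.30, edgeR adjusted p = 3.3e-07). Timp1 (ENSMUSG00000001131, chromosome X, 20870166 to 20874735), an inhibitor of metalloproteinases, rose from 0.615 ± 0.343 to 85.7 ± 35.8 CPM (log2 7.09, SE 0.44, edgeR adjusted p = 3.5e-08). Tgfb1 (ENSMUSG00000002603, chromosome 7, 25687002 to 25705077), the ligand of the pathway, rose from 15.5 ± 1.48 to 93.8 ± 15.8 CPM (log2 2.60, SE 0.22, edgeR adjusted p = 5.7e-07). Its receptor gene Tgfbr2 (ENSMUSG00000032440, chromosome 9, 116084293 to 116175360) rose by 1.12 (SE 0.26, edgeR adjusted p = 0.0025) and the effector gene Smad3 by 0.95 (SE 0.17, edgeR adjusted p = 4.1e-04). Values for Tgfbr1 (0.47), Smad2 (1.21), Smad4 (0.23) and Smad7 (−0.18, but 0.23 without fl/fl UUO replicate 1 and 0.58 with column totals) did not pass, with edgeR adjusted p from 0.0636 to 0.7925. Of 27 TGF-β ligands, receptors and Smads 10 rose (10 adjusted over the list alone, camera adjusted p = 3.1e-04, adjusted p = 0.0645 with an estimated correlation). Of 21 TGF-β responsive genes 16 rose (16 adjusted over the list alone, camera adjusted p = 6.7e-12), among them Tgfbi (a secreted matrix protein, 3.55).

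Of 20 myofibroblast and stromal genes 11 rose (11 adjusted over the list alone, camera adjusted p = 3.8e-05, adjusted p = 0.0519 with an estimated correlation), with Pdgfrb, a pericyte receptor, at 2.22 and Thy1 at 4.08. Of 9 transcription factors of epithelial-mesenchymal transition 7 rose (7 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.0645 with an estimated correlation), with Snai1 at 2.07. Of 20 basement membrane genes 6 rose and 4 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.98).

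Of 22 macrophage and monocyte genes 19 rose (19 adjusted over the list alone, camera adjusted p = 1.6e-23), among them Fcgr1 (a high-affinity IgG receptor, 4.23) and C1qc (a complement subunit, 3.804). All 7 genes of MHC class II antigen presentation rose (7 adjusted over the list alone, camera adjusted p = 1.3e-13), with Cd74, the invariant chain, going from 120.4 ± 9.77 to 1167 ± 96.1 CPM (log2 3.28, SE 0.26, edgeR adjusted p = 3.1e-07). Of 24 inflammatory cytokines and NF-κB targets 22 rose (22 adjusted over the list alone, camera adjusted p = 6.2e-28), among them the chemokine genes Cxcl2 (8.65) and Cxcl16 (2.48). Of 23 T, NK and B cell genes 17 rose (18 adjusted over the list alone, camera adjusted p = 9.6e-07, adjusted p = 0.0645 with an estimated correlation). Of 8 neutrophil genes 7 rose (7 adjusted over the list alone, camera adjusted p = 1.2e-04, adjusted p = 0.082 with an estimated correlation). Of 26 interferon response genes 21 rose (22 adjusted over the list alone, camera adjusted p = 4.5e-08, adjusted p = 0.082 with an estimated correlation). Cell cycle genes rose in 31 of 33 cases (32 adjusted over the list alone, camera adjusted p = 1.5e-14, adjusted p = 0.0645 with an estimated correlation), with the mitotic kinase gene Cdk1 at 2.65. Immediate early genes rose in 15 of 21 cases (16 adjusted over the list alone, camera adjusted p = 6.8e-10, adjusted p = 0.0645 with an estimated correlation), with the transcription factor gene Klf6 at 2.89.

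Most genes of mitochondrial metabolism fell. All 44 nuclear genes of oxidative phosphorylation were lower (44 adjusted over the list alone, camera adjusted p = 9.5e-29), with a median of −1.31. Of 13 mitochondrially encoded genes 12 fell (12 adjusted over the list alone, camera adjusted p = 6.2e-11, adjusted p = 0.0986 with an estimated correlation) as the mitochondrial share went from at least 30.8% to at most 7.67%. Of 32 genes of fatty acid oxidation 27 fell (27 adjusted over the list alone, camera adjusted p = 1.9e-11, adjusted p = 0.068 with an estimated correlation). Acadm (ENSMUSG00000062908, chromosome 3, 153922357 to 153944632), the medium-chain acyl-CoA dehydrogenase, fell from 885 ± 11.9 to 220 ± 34.5 CPM (log2 −2.01, SE 0.17, edgeR adjusted p = 5.4e-07). Of 20 genes of protein repair and the methyl cycle 12 fell and 2 rose (13 and 2 adjusted over the list alone, camera adjusted p = 5.7e-05), among them Ahcy, which hydrolyses S-adenosylhomocysteine (−2.52), and Cbs (cystathionine β-synthase, −2.39). Of 20 cholesterol biosynthesis genes 7 fell and 2 rose (7 and 2 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.2802 with an estimated correlation), a list whose median went from −0.38 to 0.36 with column totals. Of 25 genes of glycolysis and hypoxia 9 fell and 2 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.0427, adjusted p = 0.4281 with an estimated correlation), a list at −0.53 by median and 0.2 with column totals that was not called without fl/fl sham replicate 1 or fl/fl UUO replicate 2 or 3 (camera adjusted p up to 0.0722).

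The other lists moved less, or both ways. Of 24 p53 targets 11 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.0222, adjusted p = 0.0645 with an estimated correlation). Of 7 erythroid genes 5 fell (6 adjusted over the list alone, camera adjusted p = 0.0087, adjusted p = 0.2802 with an estimated correlation). Of 12 autosomal genes higher in male kidney 6 fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.2603 with an estimated correlation). Camera did not call the unfolded protein response (8 of 27 rose, 2 fell, 8 and 2 adjusted over the list alone, adjusted p = 0.0963), the circadian clock (2 of 16 rose, 5 fell, 2 and 5 adjusted over the list alone, adjusted p = 0.0794), adipose genes (5 of 9 fell, 6 adjusted over the list alone, adjusted p = 0.0562) or urothelium genes (2 of 9 rose, 2 adjusted over the list alone, adjusted p = 0.4491). Nor did it call heat shock genes (3 of 17 rose, 4 fell, 3 and 4 adjusted over the list alone, adjusted p = 0.98), whose median was −0.23 and mean 0.04, or NRF2 genes (4 of 25 rose, 7 fell, 4 and 7 adjusted over the list alone, adjusted p = 0.4668). With column totals the median rose above 0 for heat shock (0.51), NRF2 (0.68) and circadian genes (0.17). Of 3 adrenal genes 1 rose and 1 fell (1 and 2 adjusted over the list alone). Of 4 sex-specific genes (Y-linked genes and Xist) 0 passed in edgeR and 0 adjusted over the list alone, with 1 lower at an unadjusted p below 0.05 and 0 by DESeq2.

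In all, edgeR called 4031 genes higher and 3594 lower of 19256 in fl/fl UUO kidneys, and in 54.8% of the genes the libraries of the groups did not overlap, where chance gives 10%. With column totals in place of TMM, 8547 genes were higher and 906 lower, and the median of all genes shifted by 0.74. These directions are therefore relative to the bulk of expressed genes. Of the 26 lists called by camera, 11 were also called with an estimated correlation.

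**Figure D2:**
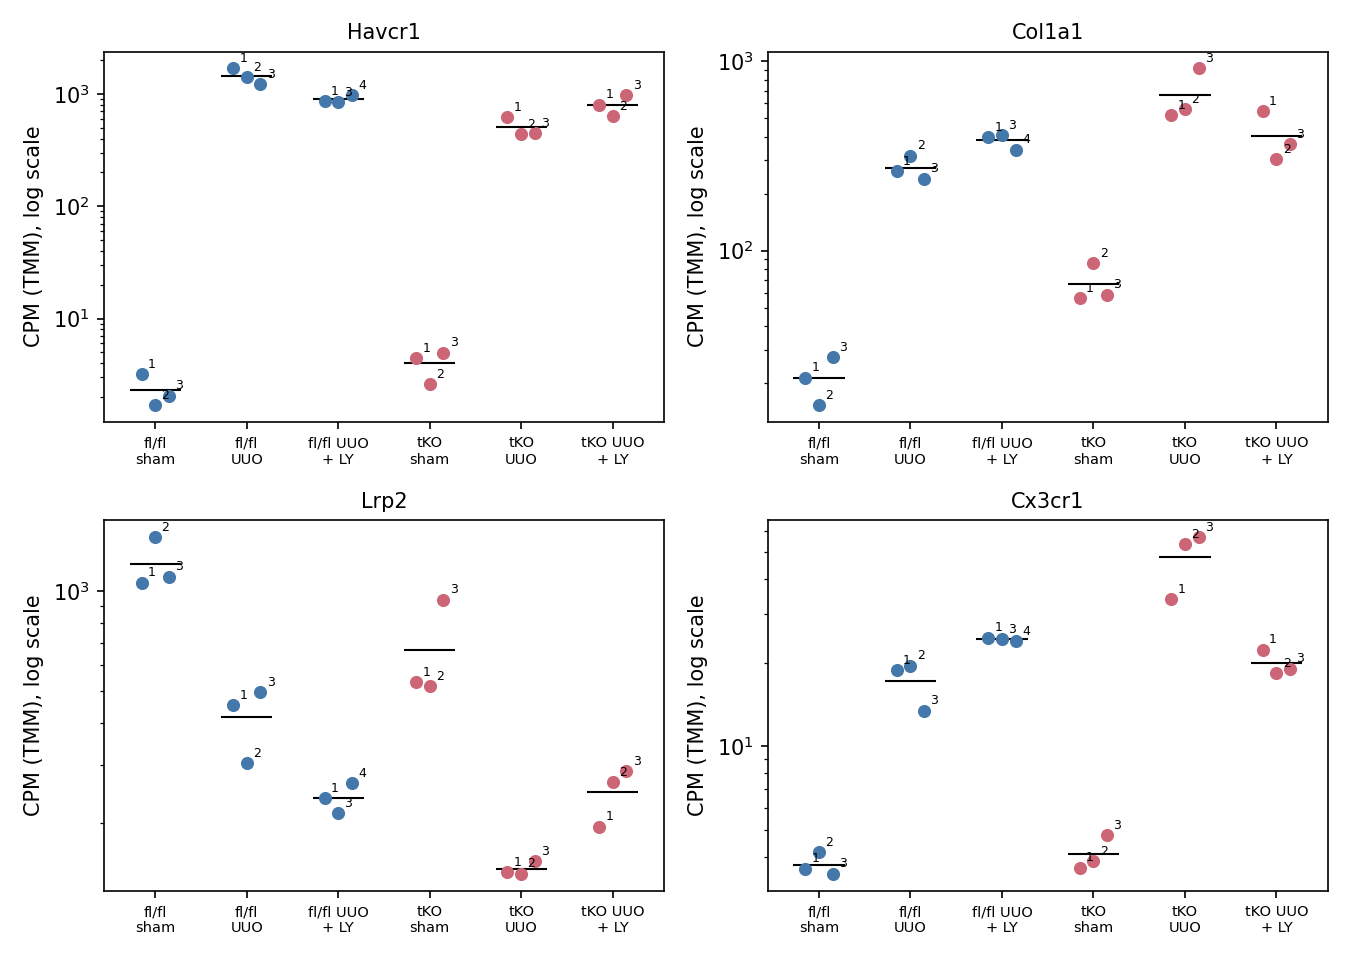
CPM (log axis) of Havcr1, Col1a1, Lrp2 and Cx3cr1 in each library of the 6 groups of the obstruction experiment, with a horizontal line at each group mean. Havcr1 lies at 1444 CPM on average in fl/fl UUO and 503 CPM in tKO UUO, and Col1a1 at 273 and 665 CPM.

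The same comparison was made in kidneys labelled tKO. Most matrix, injury and macrophage genes rose here too. Timp1 rose from 1.10 ± 0.332 to 130 ± 24.5 CPM (log2 6.84, SE 0.43, edgeR adjusted p = 4.3e-08). Havcr1 rose from 4.02 ± 1.26 to 503 ± 104 CPM (log2 6.99, SE 0.31, edgeR adjusted p = 6.8e-09), and Col1a1 from 67.0 ± 16.5 to 665 ± 219 CPM (log2 3.31, SE 0.29, edgeR adjusted p = 7.4e-07). Lox, which crosslinks collagen, rose by 3.82 (SE 0.25), and the macrophage chemokine receptor gene Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879) by 3.57 (SE 0.22). Calb1, a distal tubule calcium-binding protein, fell from 552 ± 166 to 14.6 ± 2.95 CPM (log2 −5.25, SE 0.44, edgeR adjusted p = 5.2e-07). The proximal phosphate transporter gene Slc34a1 fell from 2892 ± 361 to 427 ± 52.97 CPM (log2 −2.76, SE 0.27, edgeR adjusted p = 1.9e-06).

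Of 28 genes of fibrillar collagen and matrix 23 rose (24 adjusted over the list alone, camera adjusted p = 5.2e-17). Of 26 tubular injury genes 21 rose and 1 fell (21 and 1 adjusted over the list alone, camera adjusted p = 1.3e-22). Macrophage genes rose in 20 of 22 cases (20 adjusted over the list alone, camera adjusted p = 1.9e-28) and inflammatory cytokines in 23 of 24 (23 adjusted over the list alone, camera adjusted p = 3.4e-21). Proximal tubule genes fell in 32 of 34 cases and rose in 1 (32 and 1 adjusted over the list alone, camera adjusted p = 4.4e-22). All 16 collecting duct genes fell (16 adjusted over the list alone, camera adjusted p = 4.9e-15). Myofibroblast genes rose in 13 of 20 cases (13 adjusted over the list alone, camera adjusted p = 5.4e-06). Tgfb1 rose by 2.52 (SE 0.22, edgeR adjusted p = 8.2e-07) and Tgfbr2 by 1.02 (SE 0.26, edgeR adjusted p = 0.0051), while Smad3 was at 0.43 (SE 0.17, edgeR adjusted p = 0.0565). TGF-β ligands, receptors and Smads rose in 9 of 27 cases and fell in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0224, adjusted p = 0.1906 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 42 of 44 cases (42 adjusted over the list alone, median −0.99, camera adjusted p = 7.9e-19, adjusted p = 0.0773 with an estimated correlation), though their median was 0.03 with column totals, beside mitochondrial shares of at least 33.7% in sham and at most 16.2% in UUO. In all, 4168 genes were higher and 3729 lower by edgeR, and with column totals 11686 higher and 715 lower, with a shift of the median of all genes of 1.04. Of 4 sex-specific genes (Y-linked genes and Xist) Uty (−0.74) and Ddx3y (−0.45) fell (2 adjusted over the list alone), and the list median went from −0.36 to 0.8 with column totals. Both calls were lost without tKO sham replicate 3 or tKO UUO replicate 1 or 2, that of Uty also without tKO UUO replicate 3 (edgeR adjusted p up to 0.1177) and that of Ddx3y without tKO sham replicate 2 (edgeR adjusted p up to 0.2178). Libraries did not overlap in 48.8% of the genes.

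The interaction tested whether the response to obstruction differed between genotypes. Few single genes passed. Havcr1 rose less in tKO than in fl/fl (interaction log2 −2.29, SE 0.38, edgeR adjusted p = 0.0452). Gys1 (ENSMUSG00000003865, chromosome 7, 45434844 to 45456619), the muscle isoform of glycogen synthase, had 39.2 ± 3.47 and 34.1 ± 3.02 CPM in fl/fl sham and UUO but 54.3 ± 4.28 and 9.83 ± 1.93 CPM in tKO sham and UUO (interaction −2.26, SE 0.22, edgeR adjusted p = 3.9e-04). Slc30a7 (ENSMUSG00000054414, chromosome 3, 115938973 to 116007406), a zinc transporter of the Golgi, had 5.18 ± 0.707 CPM in tKO sham, 27.5 ± 3.86 CPM in fl/fl sham and 41.6 ± 0.897 CPM in tKO UUO (interaction 2.14, SE 0.22, edgeR adjusted p = 5.5e-04). Rarres2, the chemerin gene, differed by 1.90 and the interferon regulatory factor gene Irf1 by −1.94. Tgfb1 had an interaction of −0.08 (SE 0.30, edgeR adjusted p = 0.9487) and Tgfbr2 of −0.11 (SE 0.36, edgeR adjusted p = 0.9432).

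Of 26 tubular injury genes 1 had a lower response in tKO (2 adjusted over the list alone), with a list median of −0.68 (camera adjusted p = 1.5e-05, adjusted p = 0.5298 or above with an estimated correlation for this and all other lists of the interaction). edgeR called 8 genes (2 higher, 6 lower), DESeq2 431, and with column totals edgeR called 0 while 2423 genes had an unadjusted p below 0.05 with TMM. The count fell to 4 without fl/fl sham replicate 2 or tKO UUO replicate 2, and to 5 without fl/fl UUO replicate 1 or 2, tKO sham replicate 3 or tKO UUO replicate 3. It was 171 without fl/fl UUO replicate 3 and 293 without the library labelled tKO sham replicate 1. Havcr1 passed in 5 of the 12 fits that each left out a library, and was lost without fl/fl sham replicate 2 or 3, fl/fl UUO replicate 1 or 2, tKO sham replicate 3, or tKO UUO replicate 2 or 3 (adjusted p up to 0.126).

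Sham kidneys of the 2 genotypes were compared by their labels, including tKO sham replicate 1 in spite of its Pcmt1 level. Part of the matrix, immediate early and interferon genes were higher in tKO, and part of the genes of mitochondrial metabolism, the unfolded protein response and heat shock were lower, with no list called at an estimated correlation. Among immediate early genes, the nuclear receptor gene Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795) stood at 97.9 ± 82.8 against 4.82 ± 0.569 CPM (log2 4.34, SE 0.67, edgeR adjusted p = 0.004). Egr1 stood at 84.2 ± 56.0 against 5.51 ± 2.99 CPM (log2 3.93, SE 0.55, edgeR adjusted p = 0.0021). Col15a1, a collagen of the basement membrane zone, stood at 60.4 ± 9.45 against 15.7 ± 6.01 CPM (log2 1.94, SE 0.23, edgeR adjusted p = 0.0018). Col1a1 stood at 67.0 ± 16.5 against 21.4 ± 6.07 CPM (log2 1.65, SE 0.28, edgeR adjusted p = 0.0048). Slc30a7 had the smallest adjusted p of the named genes, at 5.18 ± 0.707 against 27.5 ± 3.86 CPM (log2 −2.41, SE 0.17, edgeR adjusted p = 4.0e-06). Ptgr2, a prostaglandin reductase, was lower by −2.54 (SE 0.46, edgeR adjusted p = 0.0065).

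Of 28 matrix genes 18 were higher (20 adjusted over the list alone, camera adjusted p = 8.4e-16, adjusted p = 0.1331 with an estimated correlation). Of 21 TGF-β responsive genes 6 were higher (9 adjusted over the list alone, camera adjusted p = 4.7e-05, adjusted p = 0.1331 with an estimated correlation). Of 26 interferon response genes 10 were higher (14 adjusted over the list alone, camera adjusted p = 7.4e-08, adjusted p = 0.1368 with an estimated correlation), among them Oasl2 at 1.60 (SE 0.25). Of 21 immediate early genes 8 were higher (14 adjusted over the list alone, camera adjusted p = 7.4e-08, adjusted p = 0.1368 with an estimated correlation). Of 33 cell cycle genes 9 were higher (20 higher and 2 lower adjusted over the list alone, camera adjusted p = 1e-06, adjusted p = 0.2723 with an estimated correlation). Of 9 urothelium genes 4 were higher (6 adjusted over the list alone, camera adjusted p = 2.2e-04, adjusted p = 0.3079 with an estimated correlation). Of 27 TGF-β ligands, receptors and Smads 2 were higher (2 adjusted over the list alone, camera adjusted p = 0.0567). Tgfb1 was at 0.19 (SE 0.22, edgeR adjusted p = 0.6085), Smad3 at 0.50 (SE 0.17, edgeR adjusted p = 0.067) and Tgfbr2 at −0.09 (edgeR adjusted p = 0.8512). Of 4 sex-specific genes Eif2s3y was higher by 0.81 (1 adjusted over the list alone, edgeR adjusted p = 0.0351), a call lost without fl/fl sham replicate 1 or 3 or tKO sham replicate 2 or 3 (adjusted p up to 0.1486).

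Nuclear oxidative phosphorylation genes were lower in 28 of 44 cases (34 adjusted over the list alone, median −0.59, camera adjusted p = 2.7e-17, adjusted p = 0.1331 with an estimated correlation), with the complex II subunit gene Sdhc at −0.66 (SE 0.11, edgeR adjusted p = 0.0046). Mitochondrially encoded genes had a median of 1.18, beside mitochondrial shares of 33.7%, 49.7% and 69.5% in the tKO sham libraries (camera adjusted p = 1.2e-04, adjusted p = 0.3329 with an estimated correlation, 0.1275 without tKO sham replicate 3). By edgeR 0 of these 13 genes passed and 12 were higher adjusted over the list alone, 12 at an unadjusted p below 0.05, while DESeq2 called 11. Fatty acid oxidation genes were lower in 14 of 32 cases (22 adjusted over the list alone, camera adjusted p = 9.7e-10, adjusted p = 0.1436 with an estimated correlation). Cholesterol biosynthesis genes were lower in 8 of 20 cases (9 adjusted over the list alone, camera adjusted p = 2.6e-07, adjusted p = 0.1331 with an estimated correlation). Proximal tubule genes were lower in 6 of 34 cases (11 adjusted over the list alone, camera adjusted p = 1.8e-06, adjusted p = 0.1959 with an estimated correlation), with the cystine transporter gene Slc3a1 at −0.92 (SE 0.15). The bile acid transporter gene Slc10a2, outside that list, was at −1.82 (SE 0.25). The unfolded protein response was lower in 9 of 27 cases (11 adjusted over the list alone, camera adjusted p = 2.7e-05, adjusted p = 0.1531 with an estimated correlation). Heat shock genes were lower in 5 of 17 cases (7 adjusted over the list alone, camera adjusted p = 7.7e-05, adjusted p = 0.1331 with an estimated correlation), with the mitochondrial chaperonin gene Hspd1 at −1.14 (SE 0.20).

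In sham kidneys edgeR called 1109 genes higher and 1266 lower, and with column totals 70 and 222, where the median of all genes shifted by −0.28. In a fit on only these 2 groups 6 genes passed, and of the genes named here only Slc30a7 and Ptgr2 did. The count was 1330, 797 and 1004 without fl/fl sham replicate 1, 2 or 3, 485 and 1145 without tKO sham replicate 2 or 3, and 4235 without the library labelled tKO sham replicate 1. Libraries of the genotypes did not overlap in 30.3% of the genes.

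After obstruction, part of the matrix and macrophage genes were higher in tKO than in fl/fl kidneys, and part of the proximal tubule and metabolic genes lower, with no list called at an estimated correlation. Col1a1 stood at 665 ± 219 against 273 ± 39.7 CPM (log2 1.28, SE 0.27, edgeR adjusted p = 0.0066). The elastin gene Eln stood at 61.3 ± 14.8 against 19.9 ± 3.66 CPM (log2 1.62, SE 0.24, edgeR adjusted p = 0.0014). Cx3cr1 stood at 48.1 ± 12.4 against 17.3 ± 3.32 CPM (log2 1.48, SE 0.19, edgeR adjusted p = 7.1e-04). The endocytic receptor genes of the proximal tubule were lower, with Lrp2 (megalin, ENSMUSG00000027070, chromosome 2, 69424340 to 69586065) at 145 ± 6.78 against 418 ± 102 CPM (log2 −1.52, SE 0.24, edgeR adjusted p = 0.0019). Cubn (cubilin, ENSMUSG00000026726, chromosome 2, 13276338 to 13491813) stood at 43.8 ± 3.05 against 132 ± 21.0 CPM (log2 −1.59, SE 0.19, edgeR adjusted p = 5.6e-04). Havcr1 was lower as well, at 503 ± 104 against 1444 ± 234 CPM (log2 −1.52, SE 0.24, edgeR adjusted p = 0.0018).

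Of 28 matrix genes 13 were higher (18 adjusted over the list alone, camera adjusted p = 1.5e-09, adjusted p = 0.1756 with an estimated correlation), among them Lox at 1.34 (SE 0.22) and Col3a1 at 1.49 (SE 0.28). Of 20 myofibroblast and stromal genes 8 were higher (11 adjusted over the list alone, camera adjusted p = 4.8e-05, adjusted p = 0.1356 with an estimated correlation), among them Vim at 1.19 and S100a4 at 1.29. Of 22 macrophage and monocyte genes 8 were higher (14 adjusted over the list alone, camera adjusted p = 7.4e-06, adjusted p = 0.1756 with an estimated correlation). Of 26 interferon response genes 10 were higher and 1 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.005, adjusted p = 0.5048 with an estimated correlation). Of 23 T, NK and B cell genes 2 were higher (2 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.4155 with an estimated correlation). Of 15 endothelial genes 3 were higher (5 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.4729 with an estimated correlation, 0.0913 at the preset one without tKO UUO replicate 3). Of 8 neutrophil genes 3 were higher (3 adjusted over the list alone, camera adjusted p = 0.0303, adjusted p = 0.4155 with an estimated correlation), a list not called without fl/fl UUO replicate 3 or tKO UUO replicate 1 (camera adjusted p up to 0.1318). TGF-β ligands, receptors and Smads were higher in 2 and lower in 1 of 27 cases (1 and 1 adjusted over the list alone, camera adjusted p = 0.6335). TGF-β responsive genes were higher in 2 and lower in 1 of 21 cases (2 higher adjusted over the list alone, camera adjusted p = 0.6117). Tgfb1 differed by 0.10 (SE 0.21, edgeR adjusted p = 0.7642), Tgfbr2 by −0.20 (SE 0.25, edgeR adjusted p = 0.6244) and Smad3 by −0.02 (SE 0.17, edgeR adjusted p = 0.9384). Pcmtd1, which encodes a protein with a PCMT-like domain, was higher by 1.49 (SE 0.28, edgeR adjusted p = 0.0043).

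Of 34 proximal tubule genes 20 were lower (26 adjusted over the list alone, median −1.09, camera adjusted p = 4.4e-16, adjusted p = 0.1356 with an estimated correlation), among them Slc3a1 at −1.16 (SE 0.15) and the gluconeogenic gene Fbp1 at −2.71 (SE 0.40). Tubular injury genes were lower in 6 of 26 cases (6 adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.4155 with an estimated correlation). Cholesterol biosynthesis genes were lower in 13 of 20 cases (15 adjusted over the list alone, camera adjusted p = 5.2e-10, adjusted p = 0.1356 with an estimated correlation), among them Sqle at −1.003 (SE 0.18). Fatty acid oxidation genes were lower in 15 of 32 cases (18 adjusted over the list alone, camera adjusted p = 1.5e-09, adjusted p = 0.2341 with an estimated correlation), with the nuclear receptor gene Ppara at −1.68. Nuclear oxidative phosphorylation genes were lower in 13 of 44 cases (16 adjusted over the list alone, camera adjusted p = 1.0e-04, adjusted p = 0.5048 with an estimated correlation), with the ATP synthase subunit gene Atp5f1a at −1.20 (SE 0.17), beside mitochondrial shares of at least 9.88% in tKO and at most 7.67% in fl/fl. The unfolded protein response was lower in 11 of 27 cases (13 adjusted over the list alone, camera adjusted p = 1.6e-06, adjusted p = 0.1786 with an estimated correlation). Heat shock genes were lower in 8 of 17 cases (8 adjusted over the list alone, camera adjusted p = 8.6e-06, adjusted p = 0.1356 with an estimated correlation), with Hspd1 at −1.30 and Hsp90aa1 at −1.97. Autosomal genes higher in male kidney were lower in 6 of 12 cases (8 adjusted over the list alone, camera adjusted p = 6.1e-05, adjusted p = 0.1928 with an estimated correlation). Of 4 sex-specific genes 0 passed in edgeR, while Eif2s3y (0.69, edgeR adjusted p = 0.0501) was higher adjusted over the list alone, the 1 gene with an unadjusted p below 0.05 and the 1 called by DESeq2. Ttll12 (ENSMUSG00000016757, chromosome 15, 83575090 to 83595157), a tubulin ligase-like gene, was lower at 2.67 ± 0.448 against 31.9 ± 3.50 CPM (log2 −3.58, SE 0.33, edgeR adjusted p = 7.4e-05).

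In obstructed kidneys edgeR called 1593 genes higher and 1858 lower in tKO, and with column totals 682 in all. The count was 1360 and 2208 without fl/fl UUO replicate 1 or 3, and 1653 and 1915 without tKO UUO replicate 2 or 3. Libraries did not overlap in 42.4% of the genes. The genotype differences in sham and in UUO kidneys share no library. Across genes, which are not independent replicates, their log2 changes had a Spearman correlation of 0.516 (jackknife SE over libraries 0.089). Of 976 genes called in both 959 had the same sign, with 370 higher in both where independent lists would give 91.7, and 589 lower in both against 122.2. For wild-type and knockout kidneys against the sham comparison, the correlation over 364 genes was 0.094 (jackknife SE 0.17).

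**Figure D3:**
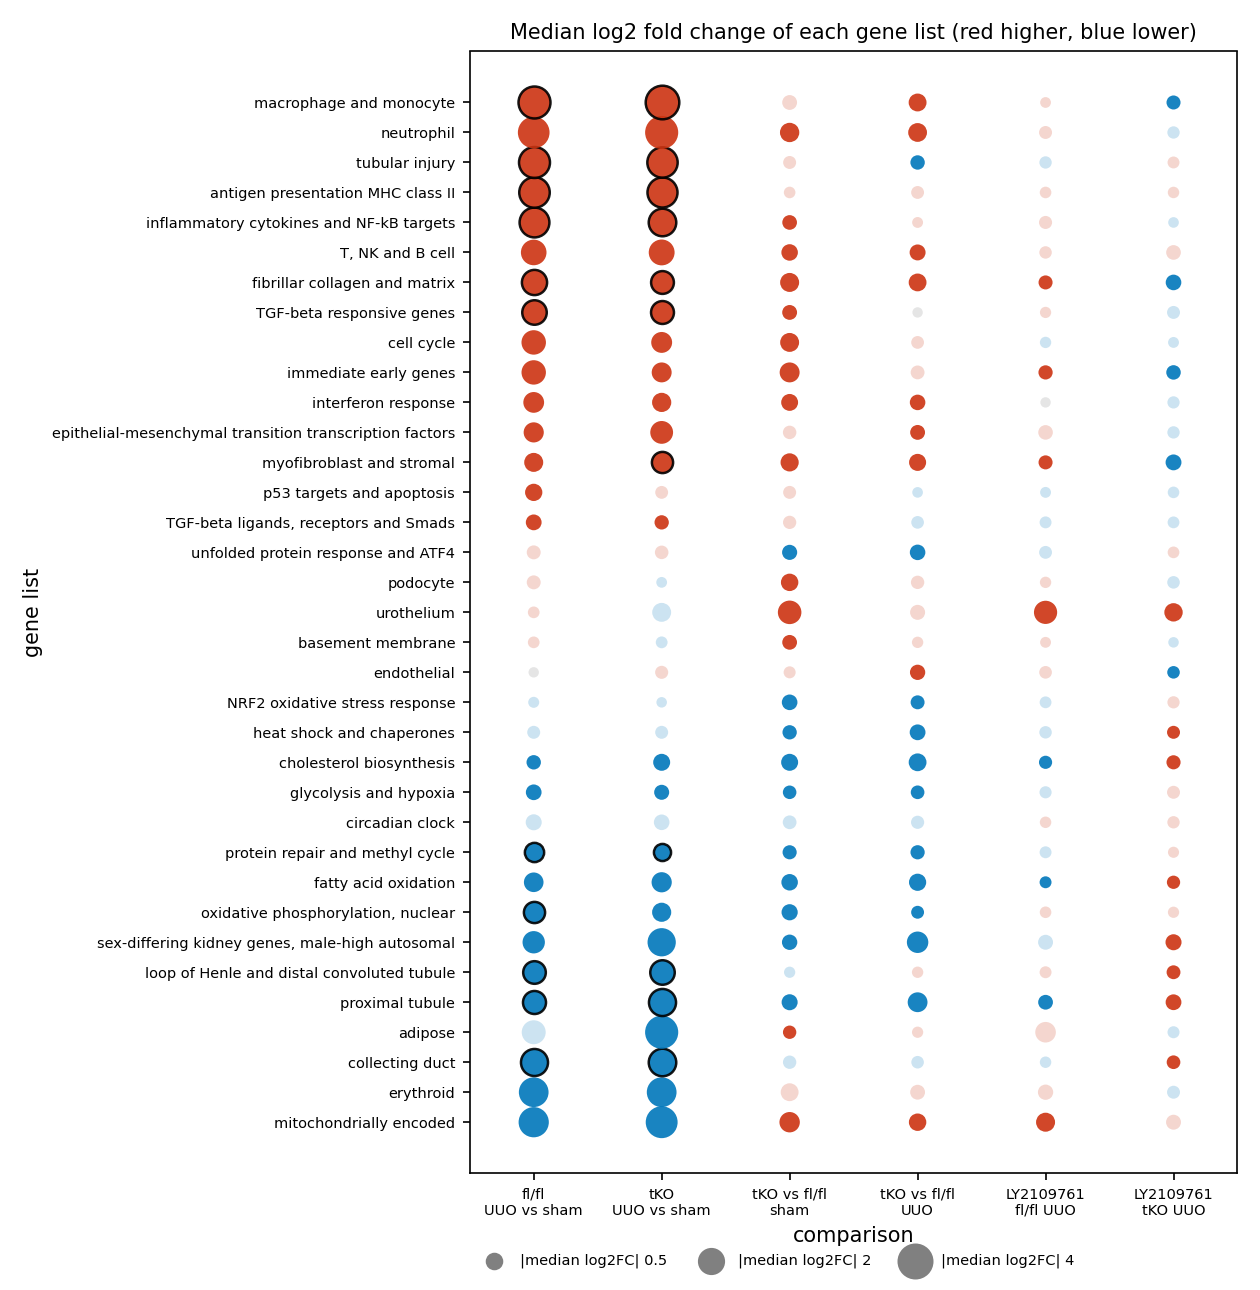
Median log2 fold change of the gene lists (vertical axis) in 6 comparisons of the obstruction experiment (horizontal axis), with dot size for its absolute value, red for higher and blue for lower, pale dots for lists that camera did not call with the preset correlation, and black outlines for lists called with an estimated correlation. The outlined dots are the 11 lists in each comparison of UUO with sham, while proximal tubule genes have medians of −1.62 and −2.4 there and −1.09 between genotypes in UUO.

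LY2109761 was compared with DMSO in obstructed fl/fl kidneys. The clearest single change was in Ttll12, which fell from 31.9 ± 3.50 to 3.01 ± 1.48 CPM (log2 −3.40, SE 0.33, edgeR adjusted p = 5.9e-04) and stayed past the threshold without any one library. Such fits cannot detect a loss of counts shared by all libraries of a group. Lum, which encodes the collagen-binding proteoglycan lumican, rose by 2.48 (SE 0.35, edgeR adjusted p = 0.0093, 0.0568 without fl/fl LY2109761 replicate 3). The urothelial plaque gene Upk2 rose by 2.64 (SE 0.59, edgeR adjusted p = 0.026), a call lost without fl/fl UUO replicate 1 or 3 or fl/fl LY2109761 replicate 1 or 3 (adjusted p up to 0.1495). Stim1, the calcium sensor of the endoplasmic reticulum, fell by 2.23 (SE 0.35, edgeR adjusted p = 0.0093, 0.0627 without fl/fl LY2109761 replicate 3). Tgfb1 was at −0.31 (SE 0.21, edgeR adjusted p = 0.4041), Tgfbr2 at −0.44 (SE 0.25, edgeR adjusted p = 0.3269) and Smad3 at 0.00 (SE 0.17, edgeR adjusted p = 0.9995). Tgfbr1, Smad2, Smad4 and Smad7 did not pass here, in tKO UUO against sham, in either genotype comparison above, in tKO with LY2109761 or in the interactions (edgeR adjusted p of 0.197 or above). Tgfbr1, which encodes a receptor kinase of the pathway, stood at 6.01 CPM in fl/fl LY2109761 replicate 3 against 84.06 and 100.62 CPM in replicates 1 and 4, and at 6.47 CPM in tKO UUO replicate 3 against 96.29 and 86.53 CPM in replicates 1 and 2.

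Of 28 matrix genes 3 were higher with LY2109761 (7 adjusted over the list alone, median 0.34, camera adjusted p = 0.0017, adjusted p = 0.8488 with an estimated correlation). Of 9 urothelium genes 3 were higher (8 adjusted over the list alone, median 1.65, camera adjusted p = 6.8e-06, adjusted p = 0.8488 with an estimated correlation). Of 13 mitochondrially encoded genes 1 was higher (1 adjusted over the list alone, camera adjusted p = 3.4e-05, adjusted p = 0.8488 with an estimated correlation), beside shares of 12.2% to 16.4% with LY2109761 and 7.43% to 7.67% without. Of 34 proximal tubule genes 2 were lower (6 adjusted over the list alone, camera adjusted p = 0.0011, 0.0557 without fl/fl UUO replicate 3, and adjusted p = 0.8488 with an estimated correlation). Of 21 TGF-β responsive genes 0 passed in edgeR and 0 adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p below 0.05 and 1 higher by DESeq2. edgeR called 486 genes higher and 505 lower, DESeq2 2055, and edgeR 25 with column totals and 54 in a fit on only these groups. The count was 2 without fl/fl LY2109761 replicate 3, 116 without its replicate 1, and 47 and 264 without fl/fl UUO replicate 1 or 2. Libraries did not overlap in 31.8% of the genes.

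In obstructed tKO kidneys LY2109761 changed few single genes. Gys1 rose from 9.83 ± 1.93 to 38.0 ± 3.98 CPM (log2 1.95, SE 0.16, edgeR adjusted p = 1.8e-05). Eeig2 (ENSMUSG00000040339, chromosome 3, 108970997 to 109027607) fell from 33.7 ± 2.38 to 0.768 ± 0.136 CPM (log2 −5.45, SE 0.35, edgeR adjusted p = 1.3e-06). Both passed without any one library, but were low in all libraries of 1 group, a loss such fits cannot detect. Cx3cr1 fell from 48.1 ± 12.4 to 19.9 ± 2.13 CPM (log2 −1.27, SE 0.19, edgeR adjusted p = 0.0211), a call lost without tKO UUO replicate 2 or 3 or tKO LY2109761 replicate 2 or 3 (adjusted p up to 0.126). Cubn rose from 43.8 ± 3.05 to 90.3 ± 17.1 CPM (log2 1.04, SE 0.18, edgeR adjusted p = 0.04) and passed in only 1 of the 6 fits that each left out a library, being lost without tKO UUO replicate 1, 2 or 3 or tKO LY2109761 replicate 2 or 3 (adjusted p up to 0.2135). Tgfb1 was at −0.37 (SE 0.21, edgeR adjusted p = 0.3787) and Tgfbr2 at 0.19 (SE 0.25, edgeR adjusted p = 0.75).

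The matrix list had a median of −0.52 (camera adjusted p = 1.4e-06, adjusted p = 0.4476 with an estimated correlation). Of its 28 genes 0 passed in edgeR and 1 was lower adjusted over the list alone, while 11 were lower at an unadjusted p below 0.05 and 3 by DESeq2. The proximal tubule list had a median of 0.54, with 1 of 34 genes higher (10 adjusted over the list alone, camera adjusted p = 1.3e-07, adjusted p = 0.4476 with an estimated correlation). Of 22 macrophage genes 1 was lower (2 adjusted over the list alone, median −0.34, camera adjusted p = 7.7e-04, adjusted p = 0.4476 with an estimated correlation, 0.1384 at the preset one without tKO UUO replicate 2). The cholesterol biosynthesis list had a median of 0.35 (5 of 20 higher adjusted over the list alone, camera adjusted p = 1e-04, adjusted p = 0.4476 with an estimated correlation), with 0 genes past the edgeR threshold, 7 higher at an unadjusted p below 0.05 and 2 by DESeq2. The urothelium list had a median of 0.88 (camera adjusted p = 0.0048, adjusted p = 0.662 with an estimated correlation, 0.065 at the preset one without tKO UUO replicate 2). Of its 9 genes 0 passed in edgeR and 0 adjusted over the list alone, with 3 higher at an unadjusted p below 0.05 and 0 by DESeq2. The endothelial list had a median of −0.19 (camera adjusted p = 0.0231, adjusted p = 0.662 with an estimated correlation) and was not called without tKO UUO replicate 3 or tKO LY2109761 replicate 3 (camera adjusted p up to 0.5425). Of its 15 genes 0 passed in edgeR and 2 were lower adjusted over the list alone, with 3 lower at an unadjusted p below 0.05 and 2 by DESeq2. edgeR called 16 genes higher and 17 lower, and 29 and 19 without the mitochondrially encoded genes, while DESeq2 called 945 and edgeR with column totals 1 higher and 2 lower. The count was 12, 6 and 17 without tKO UUO replicate 1, 2 or 3, and 282, 9 and 2 without tKO LY2109761 replicate 1, 2 or 3. Libraries did not overlap in 25.6% of the genes.

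The interaction tested whether the effect of LY2109761 differed between genotypes. Some matrix and stromal genes had a lower response in tKO and some proximal tubule genes a higher one, with no list called at an estimated correlation. Cubn went from 132 ± 21.0 to 76.98 ± 16.4 CPM in fl/fl and from 43.8 ± 3.05 to 90.3 ± 17.1 CPM in tKO (interaction 1.82, SE 0.26, edgeR adjusted p = 0.0016). Lrp2 went from 418 ± 102 to 239 ± 24.7 and from 145 ± 6.78 to 249 ± 47.7 CPM (interaction 1.58, SE 0.34, edgeR adjusted p = 0.0084). Eln went from 19.9 ± 3.66 to 48.0 ± 9.45 CPM in fl/fl and from 61.3 ± 14.8 to 34.9 ± 6.71 CPM in tKO (interaction −2.08, SE 0.34, edgeR adjusted p = 0.0023). Lum had an interaction of −3.01 (SE 0.48, edgeR adjusted p = 0.0021) and Cx3cr1 of −1.76 (SE 0.27, edgeR adjusted p = 0.0019). Eeig2 had the interaction with the smallest adjusted p of these genes, at −5.70 (SE 0.43, edgeR adjusted p = 1.7e-05), from the same tKO libraries. Tgfb1 (−0.06, SE 0.29, edgeR adjusted p = 0.9181), Tgfbr2 (0.62, SE 0.36, edgeR adjusted p = 0.2605) and Smad3 (−0.14, SE 0.24, edgeR adjusted p = 0.7531) did not pass.

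Of 28 matrix genes 8 had a lower response in tKO (14 adjusted over the list alone, median −0.86, camera adjusted p = 5.7e-06, adjusted p = 0.6005 with an estimated correlation). Of 20 myofibroblast and stromal genes 5 had a lower response (6 adjusted over the list alone, median −0.82, camera adjusted p = 1.4e-04, adjusted p = 0.5787 with an estimated correlation). Of 34 proximal tubule genes 8 had a higher response (13 adjusted over the list alone, median 0.96, camera adjusted p = 1.5e-06, adjusted p = 0.6005 with an estimated correlation). Of 20 cholesterol biosynthesis genes 5 had a higher response (8 adjusted over the list alone, median 0.65, camera adjusted p = 1.4e-04, adjusted p = 0.6005 with an estimated correlation). Of 21 immediate early genes 4 had a lower response (8 adjusted over the list alone, camera adjusted p = 0.0026, 0.0545 without fl/fl UUO replicate 3, and adjusted p = 0.7724 with an estimated correlation), with Nr4a1 at −4.06 (SE 0.85). edgeR called 1357 genes with a higher and 1309 with a lower response in tKO, 1624 in all without the low-count filter and 289 with column totals. The count was 1377 without fl/fl UUO replicate 1, 1654 and 1340 without fl/fl LY2109761 replicate 1 or 3, 1615 and 1751 without tKO UUO replicate 2 or 3, and 1662 and 1408 without tKO LY2109761 replicate 2 or 3.

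The genotypes were also compared in UUO with LY2109761. Eeig2 stood at 0.768 ± 0.136 CPM in the same tKO libraries and 30.9 ± 1.70 CPM in fl/fl (log2 −5.32, SE 0.35, edgeR adjusted p = 1.8e-06). Stim1 was higher in tKO by 2.43 (SE 0.35, edgeR adjusted p = 0.0069) and Men1, the menin gene, by 1.52 (SE 0.21, edgeR adjusted p = 0.0061). These 3 genes passed without any one library, though the call of Men1 was lost with column totals. The stress-induced gene Ddit4 stood at 28.02 ± 2.74 against 78.2 ± 4.89 CPM (log2 −1.48, SE 0.23, edgeR adjusted p = 0.0085, 0.0616 without tKO LY2109761 replicate 3). Nuclear oxidative phosphorylation genes were lower in 10 of 44 cases (23 adjusted over the list alone, median −0.41, camera adjusted p = 7.6e-10, adjusted p = 0.7689 with an estimated correlation). Immediate early genes were lower in 3 of 21 cases (6 adjusted over the list alone, camera adjusted p = 9.8e-05, adjusted p = 0.7689 with an estimated correlation). Of 28 matrix genes 1 was lower (1 adjusted over the list alone, camera adjusted p = 0.7358), and of 34 proximal tubule genes 0 passed in edgeR and 0 adjusted over the list alone, with 3 at an unadjusted p below 0.05 and 2 by DESeq2. edgeR called 171 genes higher and 402 lower, DESeq2 1486, and edgeR with column totals 11 and 12. A fit on only these groups called 237 genes and a fit without the low-count filter 222. The count was 85 and 23 without fl/fl LY2109761 replicate 1 or 3, and 36 and 14 without tKO LY2109761 replicate 2 or 3. Libraries did not overlap in 27.2% of the genes.

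In HK-2 cells, PCMT1 knockout was compared with wild type over 365 tested genes of the authors' list of changed genes, which was chosen on these libraries, so that counts from it are not independent evidence. The increases were led by EXOSC6, an RNA exosome subunit gene, at 46.8 ± 29.9 against 0.820 ± 0.163 CPM (log2 5.81, SE 0.73, edgeR adjusted p = 2.4e-04). Next was PKIA (ENSG00000171033, hg38 chromosome 8, 78516340 to 78605267), a protein kinase A inhibitor gene, at 5.27 (SE 0.27, edgeR adjusted p = 1.1e-05). The ephrin receptor gene EPHA7 (ENSG00000135333, chromosome 6, 93240020 to 93419559) rose from 2.99 ± 0.640 to 60.5 ± 3.07 CPM (log2 4.34, SE 0.18, edgeR adjusted p = 1.1e-05) and APOE (ENSG00000130203, chromosome 19, 44905791 to 44909393), the apolipoprotein E gene, by 2.33 (SE 0.12, edgeR adjusted p = 1.1e-05). APOL1 (ENSG00000100342, chromosome 22, 36253071 to 36267530) fell from 18.1 ± 4.005 to 1.34 ± 0.0354 CPM (log2 −3.74, SE 0.23, edgeR adjusted p = 1.5e-05), HTRA3, a secreted serine protease gene, by −2.70 (SE 0.14) and the methyltransferase gene NNMT by −2.11 (SE 0.16).

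Among TGF-β responsive genes listed, TGFBI fell from 2115 ± 51.3 to 1018 ± 136 CPM (log2 −1.06, SE 0.11, edgeR adjusted p = 1.0e-04), while FN1, fibronectin, rose by 1.01 (SE 0.12, edgeR adjusted p = 1.6e-04), a call lost with RLE factors. Of 3 matrix genes listed 1 rose and 2 fell (1 and 2 adjusted over the list alone), the latter being FBLN2 (−1.62) and TNC (−1.03). Both myofibroblast genes listed (ACTA2 −2.08, CNN1 −1.68) and both interferon response genes (IFIT3 −1.35, IFIT2 −1.22) fell (2 each adjusted over the list alone). Of the TGF-β ligands, receptors and Smads listed, ITGB6, which activates latent TGF-β, fell by 1.26 and BAMBI, a pseudoreceptor of the pathway, rose by 1.07, a call lost with RLE factors. edgeR called 208 genes higher and 157 lower, and the libraries of the groups did not overlap in 97% of the genes, which had been chosen for a difference on these libraries. With TMM on the listed genes 183 were higher and 158 lower, with RLE 103 and 158 and with column totals 158 and 158, as the median of all listed genes moved by −0.42, −0.82 and −0.59.

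Pcmt1 knockout and wild-type kidneys were likewise compared over 382 tested genes of a list chosen on these libraries. Nfat5 (ENSMUSG00000003847, chromosome 8, 107293470 to 107379517), the osmotic stress transcription factor gene, fell from 112 ± 9.07 to 25.02 ± 4.49 CPM (log2 −2.16, SE 0.25, edgeR adjusted p = 0.0014, SD with n = 4). C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136), complement component 3, fell from 37.5 ± 9.60 to 13.1 ± 5.70 CPM (log2 −1.52, SE 0.35, edgeR adjusted p = 0.019). Cyp26b1, a retinoic acid hydroxylase gene, rose from 2.11 ± 0.731 to 13.0 ± 9.39 CPM (log2 2.62, SE 0.47, edgeR adjusted p = 0.0117). Slc12a1 (ENSMUSG00000027202, chromosome 2, 125152505 to 125230002), the cotransporter gene of the thick ascending limb, rose from 682 ± 71.2 to 1259 ± 208 CPM (log2 0.89, SE 0.20, edgeR adjusted p = 0.019), a call lost with RLE factors. Cell cycle genes were higher in 14 of 17 listed cases (17 adjusted over the list alone), among them Cdc20 at 1.197 (SE 0.28) and Uhrf1, outside that list, at 1.37 (SE 0.32). Of the 17, 2 passed with TMM on the listed genes and 2 with RLE. All 17 lay above 0 under each scaling, but listed genes had been chosen for at least a 1.501-fold difference on these libraries. Their sign was therefore nearly fixed in advance.

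All 4 MHC class II genes listed were lower (4 adjusted over the list alone), with Cd74 at 118 ± 28.8 against 214 ± 24.0 CPM, and with column totals 2 of them passed. All 5 adipose genes listed were lower (5 adjusted over the list alone), with the lipid droplet gene Cidec at −1.90 (SE 0.57) and the complement factor D gene Cfd at −1.72 (SE 0.61). All 3 cholesterol biosynthesis genes listed were higher (3 adjusted over the list alone), of which 1 passed with TMM on the listed genes and 0 with RLE. No collagen or TGF-β list gene was among those tested. Of 3 myofibroblast genes 2 were higher and 1 lower (0 and 1 with RLE). edgeR called 177 genes higher and 78 lower, against 34 and 123 with TMM on the listed genes, 26 and 125 with RLE and 208 and 54 with column totals, as the median moved by −0.29, −0.34 and 0.11. The count was 69, 40, 142 and 44 without wild-type replicate 1, 2, 3 or 4, and 42 and 146 without knockout replicate 1 or 4. Of the genes named in these comparisons Nfat5, C3, Cyp26b1, Slc12a1, Cdc20 and Uhrf1 passed without any one library, while calls were lost for Cd74 without any 1 of the wild-type libraries or knockout replicate 1 (adjusted p up to 0.0644), for Cidec without wild-type replicate 2 or 4 or knockout replicate 1 (up to 0.0677) and for Cfd without wild-type replicate 1, 2 or 4 or knockout replicate 1 or 4 (up to 0.08). Libraries did not overlap in 44.8% of these genes, which had been chosen for a difference on the same libraries.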

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

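In this part the 11 tests by other splits of the samples, the 2 tests on Pcmt1 and the pelvis test were chosen after results were seen, while the gene length test had its prediction written earlier.

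The difference between genotypes in the response to LY2109761 reached 2666 genes. Among the named genes it was positive for Derpc (9.77), Lrrc19 (6.387), Srcap (5.542) and Adgrg1 (4.66), and negative for Eeig2 (−5.696), Golm2 (−5.12), Sumo2 (−4.289), Nr4a1 (−4.065), Meg3 (−3.876) and Ppp1cc (−3.401). Of these Srcap passed in 11 of the 12 fits that each left out a library and Sumo2 in 10, and the others in all. Less stable calls were those of Crispld2 (5.77, passed in 4 of the 12 fits), Cckar (4.965, 3 fits), Ablim1 (4.626, 3 fits), Lst1 (−3.236, 3 fits) and Fam25a (−3.051, 4 fits), and a replicate block ended those of Crispld2, Cckar and Ablim1. Nnt had 0 counts in all fl/fl libraries with LY2109761, so its fitted value of 14.101 has no fixed size. It was at least 1820-fold lower there than in fl/fl UUO with DMSO, passed in 2 of the 12 fits and not with a replicate block, and another gene model with the same symbol overlaps it.

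Camera with the preset correlation called a difference in this response for collagen and matrix (median −0.86), myofibroblast (−0.82), proximal tubule (0.96), endothelial (−0.35), macrophage (−0.55), fatty acid oxidation (0.51), heat shock (0.42), cholesterol biosynthesis (0.65), immediate early (−0.86) and male-high genes (1.06). With an estimated correlation none was called, with adjusted p = 0.6005 for matrix, proximal tubule and cholesterol genes, 0.5787 for myofibroblast genes and 0.7724 for the other 6 lists. At the preset correlation endothelial genes were called in 7 of the 12 fits that each left out a library, macrophage, heat shock and male-high genes in 8, and fatty acid oxidation and immediate early genes in 11.

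For these 2666 genes, gene length as the whole cause was argued against, since 2467 of them were called with the same sign after removing each library's trend on length, when 2668 genes were called in all. More renal pelvis in the fl/fl libraries with LY2109761 stayed open. The urothelium list had a median of −0.77 in the interaction (camera adjusted p = 0.2351), and it was also higher with LY2109761 in tKO (median 0.88, camera adjusted p = 0.0048, adjusted p = 0.662 with an estimated correlation). Of 100 splits that mixed the samples, 1 had as many calls, the real one, and the highest other gave 290, but these splits also mix the genotypes, which differed in 3451 genes in UUO, so they do not settle whether chance grouped the samples. The biological reading, that the inhibitor acts differently in tKO kidneys, was not tested apart from these.

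The difference between genotypes in the response to obstruction reached 8 genes, with Slc30a7 at 2.143, Rarres2 at 1.904, Gys1 at −2.263 and Irf1 at −1.944, which passed in all 12 fits that each left out a library. Ttll12 (−2.681) passed in 2 of them (edgeR adjusted p up to 0.1308), Adcy1 (−1.502) in 4 (edgeR adjusted p up to 0.1066, and not without the low-count filter) and Havcr1 (−2.29) in 5. Camera with the preset correlation called a difference for basement membrane (median −0.31), TGF-β ligands, receptors and Smads (−0.41), TGF-β responsive (−0.49), tubular injury (−0.68), proximal tubule (−0.47), endothelial (0.39), macrophage (0.54), inflammatory (−0.62), interferon (−0.25), nuclear oxidative phosphorylation (0.25), cell cycle (−0.55), immediate early (−0.79) and urothelium genes (−1.2). With an estimated correlation none was called (adjusted p = 0.5298 or above), and fry called 0 lists. At the preset correlation the TGF-β ligand and urothelium lists were called in 7 of the 12 fits (camera adjusted p up to 0.0974 and 0.1391), the interferon list in 5 (up to 0.1924), and the endothelial and macrophage lists in 11 (up to 0.1266 and 0.1939). Of 100 splits 6 gave at least as many calls, the highest 2526, so chance was not excluded. Splits that mix sham with UUO libraries carry the effect of obstruction.

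In comparisons of 3 with 3 libraries 10 splits exist, too few to exclude chance, and the real one was the largest in each. The real and the highest other counts were 365 and 0 in HK-2, 7625 and 2 for UUO in fl/fl, 7897 and 3 for UUO in tKO, 2375 and 1 for genotype in sham, and 3451 and 2 for genotype in UUO. They were 573 and 2 for genotype with LY2109761, 991 and 15 for LY2109761 in fl/fl, and 33 and 2 for LY2109761 in tKO. In kidney 1 of 35 splits, the real one, had as many calls (255, highest other 12), but there and in HK-2 the genes had been chosen on the same split.

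Pcmt1 stood at the fl/fl level in the library labelled tKO sham replicate 1 (49.3 CPM). An exchange of labels with a fl/fl sham library was argued against, since the lowest of those had 42.83 CPM. A fl/fl kidney labelled tKO stayed open: over 4 separating genes the library lay at a median position of 0.9 between fl/fl sham at 0 and the other tKO sham libraries at 1. Of these genes 3 lay nearer the tKO level, which goes against it, but 4 genes were too few to exclude it (fewer than the 5 of the smallest list tested), their positions ran from 0.49 to 1.06, and none was above 2.53 CPM in these sham groups. A lower rate of deletion in that kidney was not tested.

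In the kidney groups, which hold 4 libraries each, 5 of 108 sets of values (a named gene in a group) had 1 library far apart from the others, where chance gives about 1 in 20. They were Fgfr1op in knockout replicate 3 (31.32 CPM, others 9.632 to 10.43), Eva1a in knockout replicate 4 (52.73, others 13.77 to 18.69), Kcnk3 in knockout replicate 1 (3.588, others 7.053 to 7.138), Hadhb in wild-type replicate 2 (93.67, others 25.09 to 28.17) and Gdf15 in knockout replicate 3 (15.63, others 23.64 to 25.06).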

How the results depend on the processing

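In this part TMM on the listed genes and the fits without mitochondrially encoded genes were chosen after results were seen, and the cause of a change was not tested unless given.

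Column totals moved the counts of called genes to 12401 (UUO in tKO), 292 (genotype in sham), 682 (genotype in UUO), 23 (genotype with LY2109761), 25 (LY2109761 in fl/fl), 3 (LY2109761 in tKO), 0 (genotype by UUO) and 289 (genotype by LY2109761). Pcmt1 was then at 33.72 CPM in fl/fl sham, 48.85 in fl/fl UUO, 32.67 in tKO UUO and 31.83 in tKO UUO with LY2109761. With column totals the sign turned in fl/fl UUO for Ehd3 (0.13), Eif2s3y (0.59) and Tek (0.25), and in tKO UUO for Lama1 (0.16), Ehd3 (0.27), Eif2s3y (0.91), Pdk1 (0.11), Uty (0.37), Kdm5d (0.93) and Ddx3y (0.68). Without the low-count filter, where more genes were tested, counts were 1529 (genotype in sham), 222 (genotype with LY2109761), 360 and 13 (LY2109761 in fl/fl and tKO) and 1624 (genotype by LY2109761). DESeq2 gave 1486 (genotype with LY2109761), 2055 and 945 (LY2109761 in fl/fl and tKO) and 431 (genotype by UUO). Fits on only 2 groups, with fewer samples, gave 6 (genotype in sham), 237 (genotype with LY2109761), 54 and 13 (LY2109761 in fl/fl and tKO). A replicate block gave 221 (genotype with LY2109761), 6 (LY2109761 in tKO) and 41 (kidney), where RLE gave 151 and TMM on the listed genes 157. Correlations between libraries of the same number were −0.134 to 0.154 over 40 pairs in the obstruction experiment. They were −0.274 to 0.088 over 4 in kidney and −0.106 to 0.014 over 3 in HK-2.

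With an estimated correlation camera called 11 lists for UUO in fl/fl, 11 in tKO and 0 in each of the 7 other comparisons. The fry test called 0 lists for genotype with LY2109761, LY2109761 in fl/fl and in tKO and genotype by UUO, and 6 for genotype by LY2109761. With a replicate block 4 lists were called for genotype with LY2109761. Of 4747 list results under other settings 4325 were the same, 295 weaker, 126 stronger and 1 reversed. Of 22542 named gene results 20099 were the same, 2114 weaker, 319 stronger and 10 reversed. Genes called in neither fit gave 178 more sign flips.

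Leaving out 1 library at a time gave 353 to 359 genes in HK-2, 40 to 205 in kidney, 6350 to 7280 for UUO in fl/fl, 6534 to 7738 for UUO in tKO, 485 to 4235 for genotype in sham, 1360 to 2802 for genotype in UUO and 14 to 700 for genotype with LY2109761. It gave 2 to 1269 for LY2109761 in fl/fl, 2 to 282 for LY2109761 in tKO, 4 to 293 for genotype by UUO and 1340 to 2829 for genotype by LY2109761. Lists called, in the order of the 9 comparisons from UUO in fl/fl on, were 25 to 28, 25 to 27, 21 to 26, 17 to 21, 3 to 10, 7 to 11, 9 to 17, 11 to 16 and 7 to 12. The mitochondrially encoded list turned sign in genotype by UUO without tKO sham replicate 3 (direction 1, camera adjusted p = 0.0217, against −1 without fl/fl sham replicate 1, for example), and the correlation of knockout kidney with sham genotype was −0.047 to 0.158. The correlation of sham with UUO genotype differences was 0.45 to 0.538, that of UUO in fl/fl with LY2109761 in tKO −0.151 to −0.01, and that of UUO in tKO with LY2109761 in fl/fl 0.007 to 0.116.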

Other observations

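In this part no test was chosen after results were seen, as the 3 predictions were written before their tests, though the pattern itself was found in the data.

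In the obstruction experiment some genes stood at a small fraction of their usual level in single libraries. Of 12831 genes above 10 CPM, 537 spanned more than 3 log2 units within a group, with 77 in fl/fl sham, 83 in fl/fl UUO, 188 in fl/fl UUO with LY2109761, 193 in tKO sham, 174 in tKO UUO and 157 in tKO UUO with LY2109761. Assignment of reads to an overlapping gene model stayed open: of 354 with one, 120 spanned 1.5 or less after adding it. The median range was 3.26 after and 3.75 before, but genes without one could not change. The lowest library lay a median of 18 Poisson standard errors below the others. Picking genes for a range above 3 log2 units nearly fixed this, so counting noise was not separately tested. A split of counts between annotated transcripts stayed open, with more transcripts than genes of like level in 51.6% of comparisons, and no biological explanation was tested.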
